A study of Mus musculus with 6 samples.

How the data were processed

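Femur sections of 3 Prf1-/- mice were measured, 2 sections for each of 2 mice injected with B16F10 melanoma cells and for 1 uninjected mouse. The deposited matrices hold counts of decoded transcripts per feature and segmented cell. Per the labels the assay was Xenium Prime 5K with add-on genes on fixed, paraffin-embedded sections. The segmentation settings, the quality threshold for a decoded transcript and the software version are not given in the sources used here. Besides 5046 genes the features were 40 negative control probes, 21 genomic control probes, 609 negative control codewords, 7915 unassigned codewords and 8 deprecated codewords. Only genes entered the expression comparisons.

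The 6 sections held 77166, 65456, 140716, 119458, 182887 and 169216 cells, in the order injected mouse 1, injected mouse 2, uninjected mouse. Cells with 20 or more gene transcripts were kept, which left 517306 cells: 38627, 40185, 114976, 101423, 113170 and 108925 per section, with medians of 46, 46, 118, 144, 48 and 47 transcripts. Sections of the same mouse correlated at 0.991, 0.997 and 0.994 on log2 CPM (counts per 1000000 gene transcripts), and differed by more than sampling noise, with a chi-square per gene of 12.3, 33.3 and 12.8. The labels do not say whether the sections of a mouse came from separate femurs. They were treated as repeat measurements, and the mouse was the replicate.

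Whole-section expression was compared on counts summed over all cells of a mouse with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, from the 2 injected mice, and the lone uninjected mouse was assumed to vary like them. The TMM factors were 1.24, 0.888 and 0.908 and the common dispersion 0.334. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Of 25 gene lists fixed beforehand, the 21 with 5 or more tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. An estimated correlation and fry were alternatives. Both rest on the 1 residual degree of freedom and called no list, so they cannot single out which list calls are weak. The main setting uses the same fit but treats list members as nearly independent. Its p therefore reflects agreement among genes more than variation between mice. Expression within a cell class was compared in the same way on counts summed per mouse and class, adjusted within each class.

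The procedure was tested on simulated data with the design of the whole-section comparison and its common dispersion, 0.334, for every gene. Genes were drawn independently. Differences in dispersion between genes and lists of correlated genes were therefore not simulated, and the counts below do not cover them. In 5 simulations with 200 changed genes each, 0.277% of genes changed by a log2 of 1 were recovered, 1.90% of those changed by 2 and 26.2% of those changed by 4. Of 94 calls 2 were false. Among 100 lists without a change 6 had an unadjusted camera p under the threshold, and 5 of 5 shifted lists were found.

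Cells were clustered on 10000 kept cells per section. Counts were scaled to 100 per cell and log-transformed, the 2000 most variable genes were divided by the square root of their standard deviation and clipped at 5, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 followed (scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15). The remaining kept cells took the majority cluster of their 15 nearest sampled cells. A cluster was named when 3 or more markers of a cell type lay among its top 20 genes by fold over the other clusters, 2 or more of them among the top 10, and no other type had as many among the top 10. The 29 marker sets were fixed beforehand. Of 3 scalings of genes tried, the square root was kept after the data, including the section shares, had been seen. The naming rule was also set after the data were seen, as was the limit of 600 CPM of genomic control probes above which a cluster was left unnamed. Of 38 clusters, 18 were named, giving 15 classes, 7 fell under no name and 13 lay above the limit, at 824 or more against 397 or less in the others. Clusters above the limit held 39.7%, 38.8%, 9.46%, 10.3%, 2.94% and 3.34% of the kept cells of the sections. No doublet caller was run, since cells came from image segmentation.

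Class shares were taken over kept cells, with exact Clopper-Pearson intervals, and Prf1 counts with exact Poisson intervals. These intervals cover counting error only. No test was run on shares or on injected mouse 2 over injected mouse 1, and Prf1 was tested only as a gene of the whole-section edgeR fit. Classes with fewer than 200 kept cells in a mouse were not compared within class: adipocyte-like (163), megakaryocyte-like (190) and osteoblast-like (127). The melanoma-like class was not compared, since its cells in the uninjected mouse carried few pigment transcripts. Ratios of injected mouse 2 over injected mouse 1 were taken for genes with 100 or more counts.

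The groups, tests, gene lists, marker sets and most alternatives were fixed before the data were examined. The named genes were, in each direction, the 10 genes past the threshold with the largest value of the smaller absolute log2 ratio of the injected mice to the uninjected mouse, given that every injected section lay on the same side of both uninjected sections. Log2 CPM used a prior count of 2. From each list the 3 members with the highest mean level were named, within each class 4 genes per direction by the same rule, and for mouse 2 over mouse 1 the 10 largest ratios per direction without overlap. Where fewer genes passed, genes with 300 or more counts that were not past the threshold filled the places and are given by value only. List members past the threshold, and Dbp, Igfbp3, Ddit4, Fkbp5, Cxcl10 and Arg1 over all classes, were added after their values were seen. Not every gene that the rule names is reported.

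Alternatives were DESeq2 1.42.0 size factors, library totals, no filter on low counts, the 6 sections as separate libraries with and without the replicate number as a block, leaving out each section or an injected mouse, the DESeq2 Wald test, sums without melanoma-like cells or over kept cells only, other transcript minimums, resolutions and subsamples, and thinning of every cell to 20 transcripts. Added after the data were seen were sums without clusters above the genomic control limit, genes at 3 or more times the genomic control level, the count of higher genes not above melanoma-like cells, and 2 other scalings. Explanations for 3 patterns were tested against bounds written down for each, some of them only after the result was seen. Injection was first counted as excluded from the genomic control rate over all cells. It was left open again after the rates in cells with the same range of transcripts, up to 199, were seen. Cell coordinates and images were not used here.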

Results

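Femur sections from 3 perforin-deficient (Prf1-/-) mice were profiled with Xenium, an imaging assay that reads out transcripts of a fixed gene panel inside segmented cells of fixed, paraffin-embedded tissue. Perforin, the product of Prf1, is the pore-forming protein of cytotoxic lymphocytes. The injected group held 2 mice given B16F10 cells, a pigmented mouse melanoma line, and the uninjected group held 1 mouse. The injected mice are labelled bone-injected, and no sham-injected mouse was measured. Effects of the injection itself therefore cannot be told apart from effects of melanoma cells. Each mouse gave 2 sections, so 6 sections were measured on a panel of 5046 genes. Together they held 754899 cells and 73741015 gene transcripts. The sections of injected mouse 1 held 3995871 and 3787685 transcripts with medians of 20 and 26 per cell. Those of injected mouse 2 held 24197257 and 26751955 transcripts with medians of 85 and 109 per cell. The uninjected sections held 7739442 and 7268805 transcripts with medians of 28 and 30 per cell. Genomic control probes, which target intergenic DNA, gave 38.0 and 44.0 CPM per probe (counts per 1000000 gene transcripts) in the sections of injected mouse 1. The corresponding values were 4.61 and 5.63 in injected mouse 2 and 5.21 and 8.60 in the uninjected mouse.

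The first comparison asks which cell types made up the bone tissue of the injected and the uninjected mice. Melanoma-like cells, named from pigment cell genes such as Pmel, Dct and Tyrp1, made up 17.0% of kept cells in injected mouse 1, 33.5% in injected mouse 2 and 0.594% in the uninjected mouse. The difference of the injected mean from the uninjected mouse was 24.6 points, and 12.04 points at clustering resolution 2. Erythroid-like cells, defined by red cell genes such as Klf1, Ank1 and Slc4a1, made up 1.12% ± 0.973 (SD, n = 2 injected mice) against 27.6% in the uninjected mouse. Neutrophil-like cells made up 3.79% ± 2.65 against 15.4%, B precursor-like cells 1.32% ± 0.766 against 8.74%, and mature B-like cells 2.20% ± 0.0261 against 9.34%. Macrophage-like cells, led by Arg1 and Mrc1, made up 1.10% and 6.61% in the injected mice against 0.441%.

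Melanoma-marker cells were also counted without clustering, as kept cells holding 2 or more transcripts of the pigment cell genes, the list that includes the melanin synthesis enzymes Tyr, Tyrp1 and Dct. In injected mouse 1 they made up 22.2% (exact 95% binomial interval 21.8 to 22.7) and 18.3% (17.9 to 18.7) of the kept cells of its sections. In injected mouse 2 they made up 43.7% (43.4 to 44.0) and 45.9% (45.6 to 46.3). The uninjected sections gave a background of 0.0283% (0.0193 to 0.0399) and 0.0395% (0.0286 to 0.0532). Having no injected cells, they cannot measure transcripts from neighbouring melanoma cells, so the injected shares may include other cells. Per injected mouse the marker shares, 20.2% and 44.8%, exceeded those of melanoma-like clusters, 17.0% and 33.5%. After each cell was thinned to 20 transcripts the shares were 3.39%, 11.6% and 0.00720% in injected mouse 1, injected mouse 2 and the uninjected mouse. The melanoma-like clusters of the uninjected mouse carried 1532 pigment gene counts (CPM), against 33397 and 54630 in those of the injected mice.

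Among other stromal and tissue cells, fibroblast-like cells made up 10.7% ± 6.31 (SD, n = 2 injected mice) against 3.32% in the uninjected mouse. Endothelial-like cells made up 7.18% ± 4.21 against 2.66%, and skeletal muscle-like cells 7.39% ± 5.22 against 2.32%. Osteoblast-like cells, marked by the osteocalcin genes Bglap and Bglap2, made up 0.303% ± 0.201 against 1.91%. Megakaryocyte-like cells made up 0.322% ± 0.332 against 1.20%, mural-like cells 0.664% ± 0.0368 against 1.32% and 1.69% in the uninjected sections, and adipocyte-like cells 0.221% ± 0.0194 against 0.635%. For 13 of the 15 named classes the 4 injected sections lay all above or all below both uninjected sections. The exceptions were monocyte-like cells, at 3.14% and 0.901% against 3.82%, and osteoclast-like cells, at 3.26% and 2.40% against 2.27%. Sections of a mouse are repeat measurements, so this count compares 3 mice. The lone uninjected mouse would often be the highest or lowest by chance, and shares of a whole are not independent. The osteoclast-like cluster was led by Ctsk and Acp5 but also by the osteocyte and bone matrix genes Mepe, Dmp1, Spp1 and Ibsp and by Mmp13. Erythroid-like cells fell mostly in cluster 4 in the uninjected mouse (61.1% of the class) and mostly in cluster 8 in the injected mice (74.9% and 57.6%). Skeletal muscle-like cells fell mostly in cluster 5, led by Myf6 and Ttn, in the injected mice (91.5% and 93.0%) and in cluster 23, led by Myh4, in the uninjected mouse (56.9%). Clusters above the genomic control limit, which were not named, held 39.3% of the kept cells of injected mouse 1, 9.84% of those of injected mouse 2 and 3.13% of those of the uninjected mouse. The limit of 600 was applied to rates pooled over all sections. In these clusters the rate was 2898 and 2058 CPM in injected mice 1 and 2. It was 343 in the uninjected mouse, below the limit. With every cell thinned to 20 transcripts before clustering, the erythroid-like difference was -24.2 points in place of -26.5 and the neutrophil-like difference -5.09 in place of -11.6. The same thinning brought the macrophage-like difference from 3.42 to 0.0550 points and the fibroblast-like difference from 7.37 to 0.418, and turned the mural-like difference from -0.837 to 0.372 and the osteoclast-like difference from 0.554 to -0.568. It also brought the B precursor-like difference from -7.41 to -2.24, the osteoblast-like difference from -1.60 to -0.677, the endothelial-like difference from 4.52 to 2.87 and the monocyte-like difference from -1.80 to -0.654. The osteoblast-like difference was 0.154 with z-scores before clustering, and the adipocyte-like difference, -0.414, was 0.0153 with 10 or more transcripts per cell and the mural-like difference 0.273 with 50 or more. No test was run on shares, since permuting 3 mice cannot give a p below 1 in 3.

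**Figure D1:**
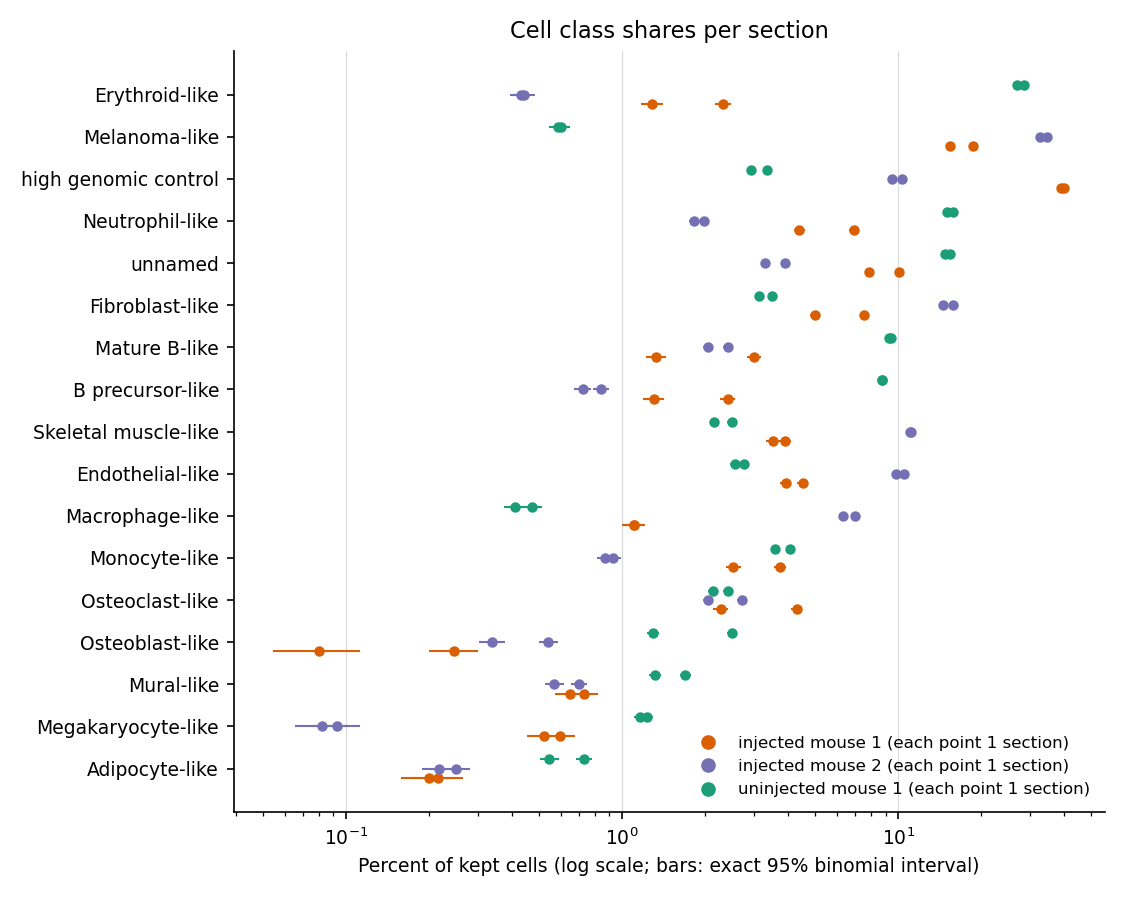
Percent of kept cells (x axis, log scale) in each cell class for the 6 sections, coloured by mouse, with exact 95% binomial intervals as bars. Erythroid-like cells lie at 26.8% and 28.5% in the uninjected sections and at 2.32% or less in the 4 injected sections.

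The second comparison asks how expression over whole sections differed between injected and uninjected bone. Of 10 tested pigment cell genes, 7 passed the edgeR threshold as higher in the injected mice. Tyr (ENSMUSG00000004651), the rate-limiting enzyme of melanin synthesis, rose by 6.88 ± 1.32 on the log2 scale (SE, edgeR, n = 2 injected mice against 1), and the melanocyte receptor gene Mc1r (ENSMUSG00000074037) by 6.42 ± 1.03. Lower genes included Epb42 (ENSMUSG00000023216), which encodes a red cell membrane protein, at -4.78 ± 0.60 and the erythroid transcription factor gene Klf1 (ENSMUSG00000054191) at -5.33 ± 0.83. The osteocalcin gene Bglap2 (ENSMUSG00000074486) fell, at -4.56 ± 0.78, as did the B cell and plasmacytoid transcription factor gene Spib (ENSMUSG00000008193), at -4.67 ± 0.77. All of these values were higher, or lower, in 4 of 4 injected sections than in both uninjected sections, as the rule that named these genes required.

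With the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, 176 of 5045 genes were higher and 226 lower in the injected mice, and 795 had an unadjusted p under the same threshold. The median log2 fold change of all genes was 0.51 after TMM scaling. It was 0.25 with DESeq2 size factors and 0.74 with library totals, so the balance of higher and lower genes depended on the scaling: 52 and 106 genes passed with the first, 468 and 365 with the second.

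Among the 10 higher genes named by the fixed rule, the smallest adjusted p was that of the homeobox gene Rhox5 (ENSMUSG00000095180), with a log2 fold change of 6.67 ± 0.87 and an adjusted p of 4.7e-11 in edgeR. Its level was 233 to 320 CPM in the injected sections and 2.79 in each uninjected section. The synaptotagmin gene Syt4 (ENSMUSG00000024261) rose by 7.13 ± 1.29, the melastatin channel gene Trpm1 by 6.80 ± 1.29 and the melanocyte lineage transcription factor genes Pax3, Tfap2a and Sox10 by 6.40, 6.26 and 5.74. Mlph, which encodes the melanosome transport protein melanophilin, rose by 6.07 and Oca2, a melanosome ion transport gene, by 6.05. Among the 10 lower genes, the ankyrin gene Ank1 (ENSMUSG00000031543) fell (-5.42 ± 0.88), as did the beta spectrin gene Sptb (-4.27), the adducin gene Add2 (-4.53) and the erythropoietin receptor gene Epor (-4.42). Tent5c, a poly(A) polymerase gene, fell by 4.75. The adjusted p (edgeR) of the genes named by the rule ran from 1.2e-11 for Epb42 to 6.0e-04 for Mlph. Without the cells of melanoma-like clusters 39 genes were higher and 85 lower, and without the cells of clusters above the genomic control limit 413 were higher and 295 lower.

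**Figure D2:**
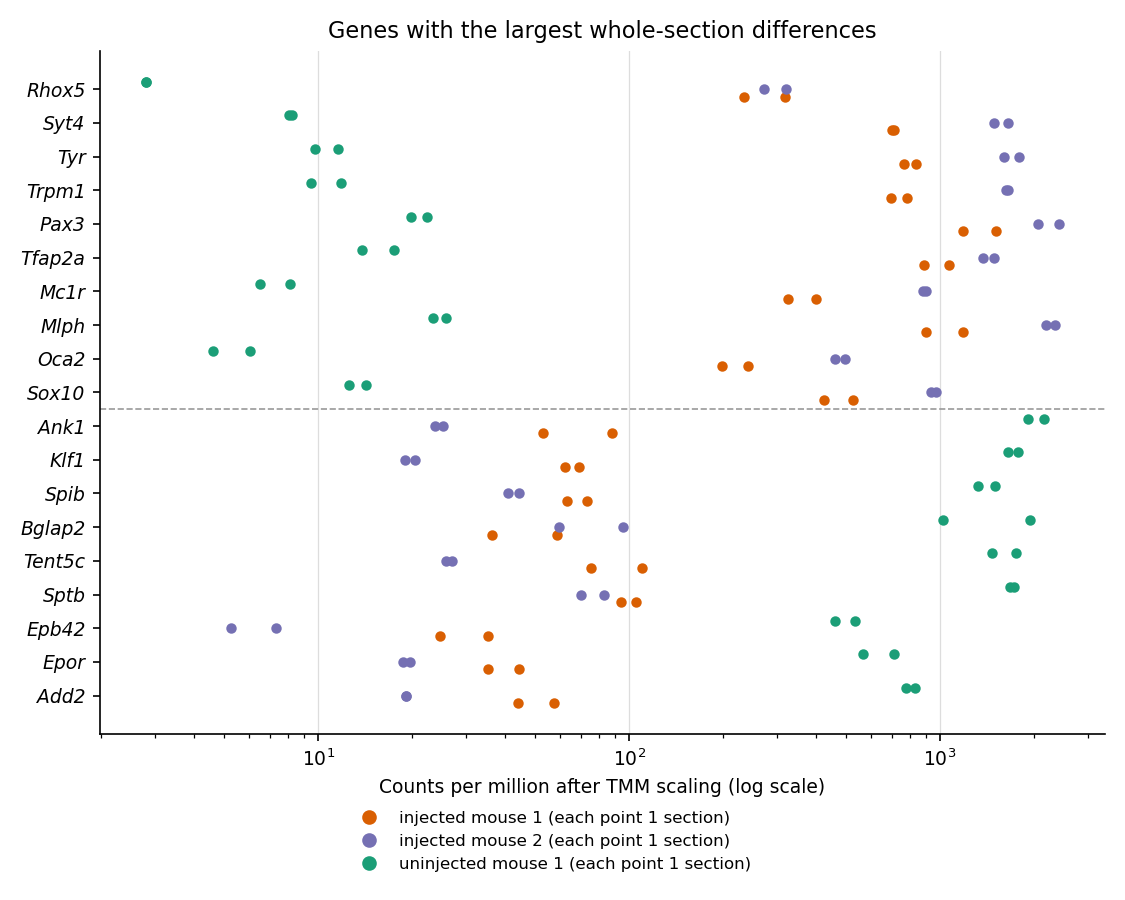
CPM after TMM scaling (x axis, log scale) of genes named by the fixed rule; each point is 1 section, coloured by mouse, and the dashed line parts the higher from the lower genes. Rhox5 lies at 233 to 320 in the 4 injected sections and at 2.79 in both uninjected sections, and Klf1 at 69.0 or less against 1654 and 1787.

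The gene lists fixed for this tissue ask which programmes moved together. The erythroid list had the largest shift downward: its median log2 fold change lay -4.86 from that of all genes, 8 of its 10 tested members fell and none rose, and 9 fell when adjusted over the list alone. Gata1 and Tal1, transcription factor genes of the erythroid lineage, fell, at -4.22 ± 0.59 and -3.48 ± 0.58. The anion exchanger gene Slc4a1 did not pass the edgeR test (-5.76 ± 2.65, adjusted p = 0.221) although its level was 27018 and 29034 CPM in the uninjected sections and 102 to 990 in the injected ones. The B lineage list lay -3.57 from the median of all genes, and 9 of 11 members fell, both over all genes and adjusted over the list alone. Its lower members included Rag1, the V(D)J recombinase gene, at -3.65 ± 0.59, and Pax5, the B cell identity factor gene, at -3.36 ± 0.60. Adjusted p in the camera test was 6.4e-29 for the erythroid list and 7.4e-17 for the B lineage list. Both calls were lost with an estimated correlation (camera adjusted p = 0.852 for each). That setting rests on 1 residual degree of freedom and called no list at all. The main camera test used the same fit, and its preset correlation of 0.01 treats members as nearly independent. Its small p therefore reflects agreement among genes more than variation between mice. The sections of injected mouse 1, in which these lists were also low, carried the genomic control rates of 38.0 and 44.0 given above.

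The pigment cell list lay 6.10 above the median of all genes. Of its 10 tested members 7 rose and none fell, and 10 rose when adjusted over the list alone. Mitf, the master transcription factor gene of melanocytes, rose by 4.14 ± 0.86 and the melanosome transporter gene Slc45a2 by 6.18 ± 1.11. Pmel, Tyrp1 and Dct were the members with the highest level but did not pass over all genes, with log2 fold changes of 6.89 ± 3.02, 6.93 ± 2.69 and 6.85 ± 2.53 and an edgeR adjusted p of 0.182 for Pmel and 0.0753 for Dct. The list had a camera adjusted p of 5.4e-28, and adjusted p = 0.852 with an estimated correlation. Melanoma-marker cells made up 20.2% and 44.8% of the kept cells of the same injected mice.

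Bone and marrow support genes lay below the median of all genes. Osteoblast and bone matrix genes lay -1.35 from it: Bglap2, Bglap (-3.97 ± 0.77) and Runx2 (-1.91 ± 0.62), the master regulator gene of osteoblast differentiation, fell among 14 members, and the same 3 members counted adjusted over the list alone. Marrow niche factors lay -1.35 from it, with 3 of 14 lower and 5 adjusted over the list alone: the adipokine gene Adipoq fell (-2.30 ± 0.56), as did the leptin receptor gene Lepr (-1.71 ± 0.57) and Igf1 (-1.67 ± 0.56). Cxcl12, the chemokine gene that retains blood progenitors in the marrow, had a log2 fold change of 0.54 ± 1.73. It had the most counts of any gene in both sections of injected mouse 1 (33654 and 36187). With Lif, Diras1 and Defa5 it was among the genes leading several clusters above the genomic control limit. Without those clusters its value was -0.074. Osteoclast genes lay -1.07 from the median of all genes, with 2 of 9 lower and 3 adjusted over the list alone: the integrin gene Itgb3, which platelets also express, fell (-2.36 ± 0.59), as did Nfatc1, the master regulator gene of osteoclast differentiation (-1.85 ± 0.64). Ctsk, the collagen-degrading protease of osteoclasts, had a value of -0.56 ± 0.81. Camera adjusted p was 0.000615 for the osteoblast list, 0.0191 for the niche list and 0.0244 for the osteoclast list, and each had adjusted p = 0.852 with an estimated correlation. Nfatc1 lost its edgeR call with DESeq2 size factors (adjusted p = 0.298), and the niche list did with library totals (adjusted p = 0.0640). Without the cells of melanoma-like clusters no camera call of the osteoblast, niche and osteoclast lists remained (adjusted p = 0.0994, 0.376 and 0.376).

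Proliferation genes lay -1.75 from the median of all genes with a camera adjusted p of 0.000325, and adjusted p = 0.852 with an estimated correlation. Of 15 members only the cyclin gene Ccna2 fell (-2.28 ± 0.64), over all genes and adjusted over the list alone, while Mki67 and Top2a had values of -2.49 ± 1.11 and -1.35 ± 1.13. Macrophage genes lay -1.29 from it with a camera adjusted p of 0.0244 and adjusted p = 0.852 with an estimated correlation. Members went both ways: Cd5l and the iron exporter gene Slc40a1, both typical of macrophages that recycle red cells, fell, at -3.44 ± 0.58 and -2.82 ± 0.58, and the receptor kinase gene Mertk rose by 3.34 ± 1.11. Adjusted over the list alone 1 member rose and 3 fell. Mertk was also among the genes leading a melanoma-like cluster, and it lost its edgeR call with DESeq2 size factors (adjusted p = 0.323). The macrophage list lost its camera call without the clusters above the genomic control limit (adjusted p = 0.0917), with library totals (0.0640) and without melanoma-like cells (0.306).

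Immediate early and stress genes lay 0.96 above the median of all genes: the transcription factor gene Fos rose by 2.16 ± 0.70, none of the 10 members fell, and 5 rose when adjusted over the list alone. Hypoxia and glycolysis genes lay 0.84 above it: the glucose transporter gene Slc2a1 rose by 2.37 ± 0.66, 1 of 11 members over all genes and adjusted over the list alone, while Pgk1 and Vegfa had values of 2.19 ± 1.40 and 0.92 ± 0.83. Matrix remodelling genes had a median only 0.06 above it, but 3 of 14 members rose over all genes and adjusted over the list alone, among them the metalloproteinase inhibitor gene Timp1 by 3.33 ± 0.71 and the collagen cross-linking enzyme gene Lox by 1.97 ± 0.66. Camera adjusted p was 0.00719, 0.0113 and 0.0250 for the immediate early, hypoxia and matrix lists. None was called with an estimated correlation (adjusted p = 0.852 with an estimated correlation for each). Without the cells of melanoma-like clusters the hypoxia list had a camera adjusted p of 0.0866. The matrix list lost its call, and its median turned below that of all genes, without injected mouse 1 replicate 1 (-0.087, camera adjusted p = 0.0971) and without injected mouse 2 replicate 1 (-0.052, adjusted p = 0.0710).

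The remaining lists were not called by camera, but single members moved. Among inflammatory cytokines and chemokines the monocyte-attracting chemokine genes Ccl2 and Ccl7 rose by 3.69 ± 0.72 and 2.60 ± 0.69, and 3 of 16 members rose adjusted over the list alone. Among suppressive myeloid genes Arg1, the arginine-degrading enzyme of suppressive macrophages, rose by 4.65 ± 0.85 and Tgfb1 fell by 1.91 ± 0.57 of 16, over all genes and adjusted over the list alone. Gpnmb, which melanoma cells also express, had a value of 6.84 ± 2.92 (edgeR adjusted p = 0.161). In the interferon gamma list Cxcl10, a chemokine gene that attracts activated T cells, rose by 4.82 ± 0.97 of 11 members, with 1 higher and 1 lower adjusted over the list alone. In the checkpoint list Vsir, which encodes an inhibitory receptor of T and myeloid cells, fell by 2.51 ± 0.58 of 16 members, with 2 lower adjusted over the list alone. In the osteoclast-regulating list Tnfrsf11b, the decoy receptor gene osteoprotegerin, rose by 2.80 ± 0.76 of 12 members, over all genes and adjusted over the list alone, but not with DESeq2 size factors (edgeR adjusted p = 0.0814). Among skeletal muscle genes Myh2, a fast myosin gene, fell by 2.58 ± 0.84 of 6 members, and also adjusted over the list alone. No member passed, over all genes or adjusted over the list alone, among 10 type I interferon genes, 10 cytotoxic effector genes, 16 T and NK lineage genes and 9 endothelial genes. Camera adjusted p of these 10 lists ran from 0.201 to 0.989, and from 0.852 to 0.991 with an estimated correlation.

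In the checkpoint and cytotoxic effector lists the median lay above that of all genes, by 0.28 and 0.15, while the mean and the camera direction were downward. In the type I interferon and osteoclast-regulating lists the median and the mean lay below it, by -0.11 and -0.35 for the medians, while the camera direction was upward. In the T and NK list the members had a median of 0.26 in injected mouse 1 and -1.17 in injected mouse 2 over the uninjected mouse, and the cytotoxic effector list had 1.35 and -0.67. These low-count lists sat beside the genomic control rates of 38.0 and 44.0 in injected mouse 1. Without the clusters above the genomic control limit the checkpoint list turned to -0.22 and the cytotoxic effector list to -0.23. A further 4 lists had fewer than 5 members on the panel and were not tested as lists. Of these, the neutrophil granule genes Mpo and Cd177 fell (-3.83 ± 1.28 and -3.78 ± 0.77), as did the platelet genes Itga2b and Tubb1 (-3.04 and -2.65) and the MHC class II peptide-loading gene H2-DMb2 (-1.93 ± 0.61), while the MHC class I peptide transporter gene Tap1 had a value of -1.20 ± 0.57. Mpo lost its edgeR call with DESeq2 size factors (adjusted p = 0.119), as did H2-DMb2 (0.0625). Of the members named above as higher or lower, H2-DMb2, Ccl7, Mpo, Mertk, Nfatc1, Tnfrsf11b, Myh2, Ccna2, Tgfb1, Runx2, Itgb3, Igf1, Lepr, Slc2a1, Lox, Timp1 and Fos had no edgeR call with DESeq2 size factors. Without the cells of melanoma-like clusters H2-DMb2, Vsir, Mpo, Mertk, Itga2b, Tubb1, Nfatc1, Tnfrsf11b, Myh2, Tgfb1, Runx2, Itgb3, Adipoq, Igf1, Lepr, Slc2a1 and Fos had none. List members named here other than the 3 with the highest mean level in each list and the 20 genes of the fixed rule were chosen after their values were seen.

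**Figure D3:**
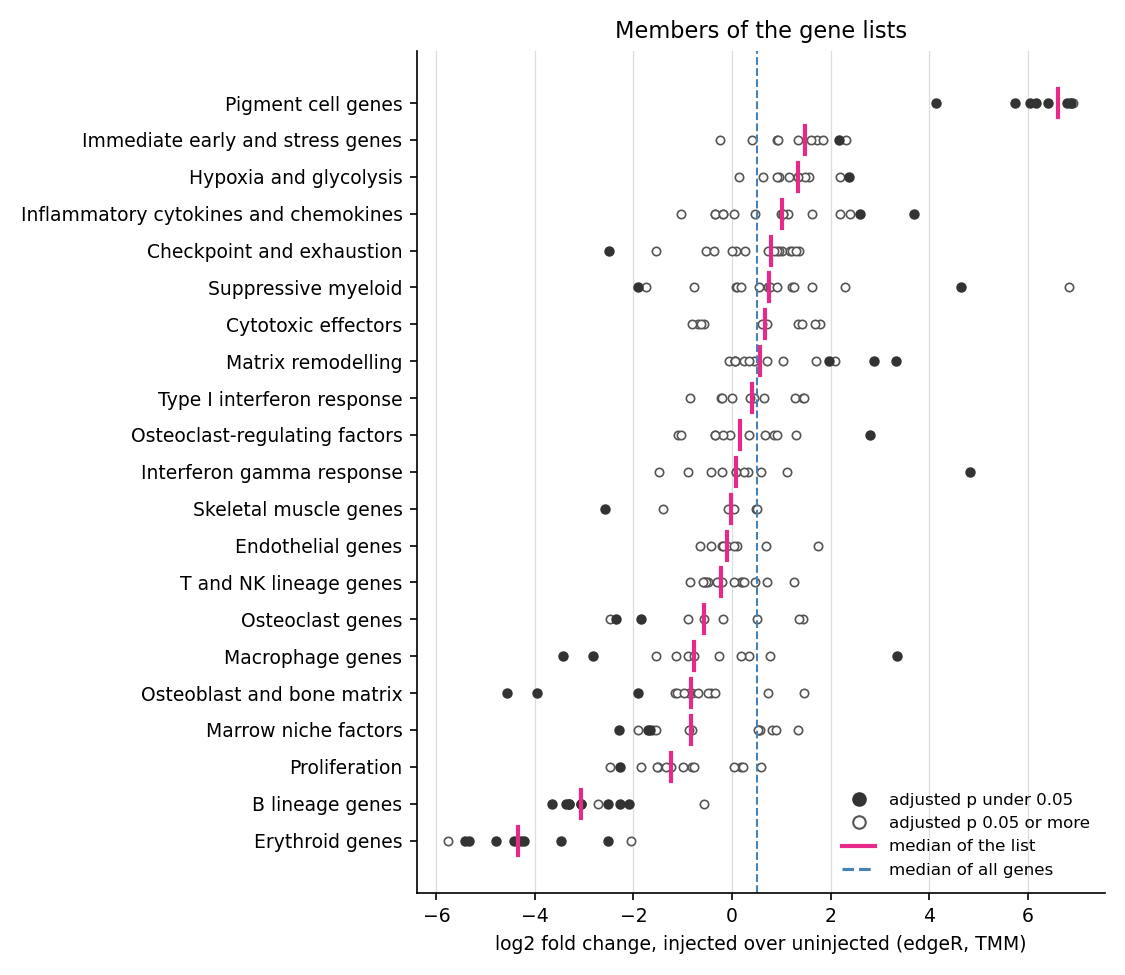
Log2 fold change of each tested list member (x axis, injected over uninjected, edgeR with TMM scaling) for the 21 lists, with filled points past the adjusted threshold, the list median as a bar and the median of all genes, 0.51, as a dashed line. The erythroid members lie between -5.76 and -2.05 and the pigment members between 4.14 and 6.93.

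The third comparison asks which genes differed inside each cell class. In endothelial-like cells the serine protease inhibitor gene Serpina3n rose by 3.04 ± 0.40 and Timp1 by 3.17 ± 0.53. In fibroblast-like cells the acute phase gene Saa1 rose by 4.77 ± 0.73, Timp1 by 2.74 ± 0.39 and the haem oxygenase gene Hmox1 by 2.68 ± 0.44 (SE, edgeR, n = 2 injected mice against 1). In skeletal muscle-like cells Serpina3n rose by 7.52 ± 0.90 and the lipase inhibitor gene Angptl4 by 3.62 ± 0.39. The calls of this class were lost without injected mouse 2 replicate 1 and without either uninjected replicate. In monocyte-like cells the matrix genes Thbs1 and Vcan rose by 3.70 ± 0.53 and 3.11 ± 0.55.

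Over 11 classes the edgeR test gave 618 higher and 683 lower genes, counted per class, with adjustment within each class. Endothelial-like cells gave 204 higher and 199 lower of 3363 tested, and skeletal muscle-like cells 2 higher and 18 lower of 3090, where 532 genes had an unadjusted p under the same threshold. The counts per class moved with single sections: without injected mouse 1 replicate 2 endothelial-like cells gave 114 and 124 and fibroblast-like cells 245 and 240, in place of 51 and 68. Without uninjected replicate 1 the counts of fibroblast-like and of macrophage-like cells moved the other way and fell below their main values. Pigment cell genes rose inside several other classes: 10 of 10 tested in endothelial-like and in osteoclast-like cells, 9 of 10 in fibroblast-like, 8 of 9 in macrophage-like and in mural-like and 7 of 9 in neutrophil-like cells. The counts were 3 of 4 in B precursor-like, 3 of 6 in monocyte-like, 2 of 8 in erythroid-like and 1 of 9 in mature B-like cells, and none of 10 was called in skeletal muscle-like cells. Of the 618 higher calls, 232 were of genes that the melanoma-like cells of the same mouse did not carry at a higher level than the class, a count chosen after the data were seen. Apart from pigment genes, the genes named as higher in this comparison meet that criterion.

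Among immune cells, macrophage-like cells of the injected mice carried the interleukin 1 receptor antagonist gene Il1rn at 336 to 549 CPM and the macrophage elastase gene Mmp12 at 267 to 776, and both rose (edgeR adjusted p = 0.00540 and 0.0108) from levels listed at 0 in both uninjected sections. In the same class the red cell anion exchanger gene Slc4a1 fell (-6.34 ± 0.53), as did the circadian output gene Dbp (-4.64 ± 0.42). Monocyte-like cells showed higher Shtn1 (3.43 ± 0.56) and F11r (3.83 ± 0.81), a junctional adhesion molecule gene, and lower Itga1 (-2.04 ± 0.44). Neutrophil-like cells showed higher Vcan (3.08 ± 0.51) and Igfbp3 (2.66 ± 0.50), which encodes an insulin-like growth factor binding protein. Mature B-like cells showed higher Fkbp5 (2.37 ± 0.45), a glucocorticoid-induced chaperone gene, and lower Igll1 (-4.29 ± 0.88), the surrogate light chain gene of B precursors. B precursor-like cells showed higher Ddit4 (2.92 ± 0.57), a stress-induced inhibitor gene of mTOR signalling, and lower Sox4 (-3.19 ± 0.58) and Ccna2 (-2.99 ± 0.55). In B precursor-like cells the edgeR test called 44 genes higher and 68 lower on all sections. Without injected mouse 2 replicate 2 it called 0 higher and 0 lower, with 149 at an unadjusted p under the same threshold. The DESeq2 Wald test on all sections called 6 higher and 20 lower in this class. Erythroid-like cells showed higher Igfbp3 (3.10 ± 0.52) and lower Cdk1 (-2.16 ± 0.42) and Cdca8 (-2.20 ± 0.43), both cell division genes. Cluster 4 held 25.1% and 42.4% of this class in the injected mice and 61.1% in the uninjected mouse. A change in the mix of clusters was not separated from a change within cells. Dct, a pigment gene at 9172 and 11274 CPM in melanoma-like cells of the injected mice, rose by 4.48 ± 0.56 in erythroid-like and 4.01 ± 0.58 in neutrophil-like cells.

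In bone and support cells, osteoclast-like cells showed higher Arg1 (3.76 ± 0.60) and the lipid droplet gene Plin2 (2.56 ± 0.44), and lower Col10a1 (-4.77 ± 0.40), the collagen X gene of hypertrophic cartilage, and Myb (-3.98 ± 0.44). Fibroblast-like cells showed lower Adipoq (-4.77 ± 0.33), the lipid droplet gene Plin1 (-4.43 ± 0.32) and Car3 (-4.47 ± 0.32), all among the genes leading the adipocyte-like cluster. Endothelial-like cells showed higher Trim63 (3.73 ± 0.55), a ubiquitin ligase gene among those leading a skeletal muscle-like cluster, and lower Cyp2e1 (-3.79 ± 0.36), which led the adipocyte-like cluster. Skeletal muscle-like cells showed lower Dbp (-5.09 ± 0.40), the water channel gene Aqp4 (-5.56 ± 0.54) and Mettl21c (-5.46 ± 0.54). Cluster 5 held 91.5% and 93.0% of this class in the injected mice and 43.1% in the uninjected mouse, and this change in mix was not separated. In the same class Cxcl10 was not past the edgeR threshold, at 5.71 ± 0.91 with an adjusted p of 0.0729. Cxcl10 stood at 516 and 1227 CPM in melanoma-like cells of the injected mice. Mural-like cells showed higher Ddit4 (3.05 ± 0.69) and lower Tent5c (-3.95 ± 0.69). Erythroid genes were among the lower genes of non-erythroid classes: Klf1 fell in B precursor-like (-3.37 ± 0.56), mature B-like (-3.91 ± 0.69), monocyte-like (-3.27 ± 0.67) and neutrophil-like cells (-2.89 ± 0.46). Several other genes named within a class were among those leading clusters of another class, such as Arg1 and Thbs1 (macrophage-like) and Igfbp3 (endothelial-like). The criterion for naming higher genes compared them only with melanoma-like cells, and no transcripts were removed. Leaving out uninjected replicate 1 lowered the totals to 338 higher and 439 lower genes, and the DESeq2 Wald test gave 342 and 304. The mural-like genes named here lost their calls with library totals. In skeletal muscle-like cells edgeR called 0 genes higher and 0 lower without injected mouse 2 replicate 1 and without either uninjected replicate, with 494 to 509 at an unadjusted p under the same threshold, against 45 higher and 70 lower by the DESeq2 Wald test on all sections. Without uninjected replicate 1 the calls of Saa1, Timp1 and Hmox1 in fibroblast-like cells and of Il1rn and Mmp12 in macrophage-like cells were lost too (edgeR adjusted p = 0.0626, 0.0556, 0.0669, 0.0561 and 0.0935), those of Saa1 and Mmp12 also without uninjected replicate 2 (0.0581 and 0.0717). With 50 or more transcripts per cell Adipoq, Car3, Timp1 and Hmox1 in fibroblast-like and Dct, Cdk1 and Cdca8 in erythroid-like cells had no edgeR call. The DESeq2 Wald test did not call Sox4 in B precursor-like, Cdca8 in erythroid-like, Klf1 and Itga1 in monocyte-like and Ddit4 and Tent5c in mural-like cells.

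The fourth comparison sets injected mouse 2 against injected mouse 1, to describe how the injected mice differed. Among the genes higher in mouse 2 were Nrp2 (ENSMUSG00000025969), a vascular guidance receptor gene, by 2.46 on the log2 scale, the chemokine gene Ccl2 (ENSMUSG00000035385) by 2.37 and Arg1 (ENSMUSG00000019987) by 2.27. The pigment gene Tyrp1 was higher by 2.42, the retinoic acid synthesis gene Aldh1a2 by 2.40, the myosin gene Myh2 by 2.08, Col18a1 by 2.00, Thbs1 by 1.97 and the transferrin receptor gene Tfrc by 1.94. The red cell gene Slc4a1 (ENSMUSG00000006574) was higher in mouse 1, at -3.07. The other genes with the largest ratios toward mouse 1 lay between -3.07 and -2.80 and are not typical of bone: the iron hormone gene Hamp, the neural genes Hes5 and Sox3, the liver transcription factor genes Onecut1 and Nr1i3, and Uba1y, Ucn3, Nlrp6 and Irx4. Their levels were 5.85 to 50.3 CPM in the sections of mouse 1, beside a genomic control rate per probe of 38.0 and 44.0.

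Of 5039 genes with 100 or more counts, 340 were at least doubled in mouse 2 and 1712 in mouse 1 with no overlap between the sections of the 2 mice, sections being repeat measurements of a mouse. By list, the median ratio of mouse 2 over mouse 1 was 1.18 for pigment cell genes and 1.03 for hypoxia and glycolysis genes. It was -1.62 for erythroid genes, -1.52 for T and NK lineage genes, -1.91 for cytotoxic effectors and -1.30 for inflammatory cytokines and chemokines, Ccl2 being among the members that went the other way. These lower values sat beside genomic control rates of 38.0 and 44.0 CPM per probe in mouse 1 and 4.61 and 5.63 in mouse 2. Without the cells of melanoma-like clusters the ratio was 1.44 for Nrp2, 0.62 for Tfrc and 3.01 for Aldh1a2. Library totals in place of TMM gave 57 genes doubled in mouse 2 and 2011 in mouse 1. No test was run, since this sets 1 mouse against 1.

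The last comparison reads Prf1 itself (ENSMUSG00000037202), since every mouse is labelled Prf1-/-. Prf1 transcripts were counted in all 6 sections: 53.1 (exact 95% Poisson interval 46.2 to 60.7) and 56.2 (48.9 to 64.3) CPM in injected mouse 1, 41.8 (39.2 to 44.4) and 38.3 (36.0 to 40.7) in injected mouse 2, and 68.1 (62.4 to 74.2) and 73.2 (67.1 to 79.7) in the uninjected mouse. These levels were 39.4 to 257 times the mean negative control probe. They were 1.40 and 1.28 times the mean genomic control probe in injected mouse 1, 9.07 and 6.80 times in injected mouse 2, and 13.1 and 8.51 times in the uninjected mouse. The log2 ratio of the injected mean to the uninjected mouse was -0.58 on the CPM scale and 0.84 per cell, so its direction depended on the scale. By edgeR over whole sections the value was -0.80 ± 0.81 (adjusted p = 0.915). Which part of the gene the probes target is not given in the sources used here, and no wild-type mouse was part of the series.

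**Figure D4:**
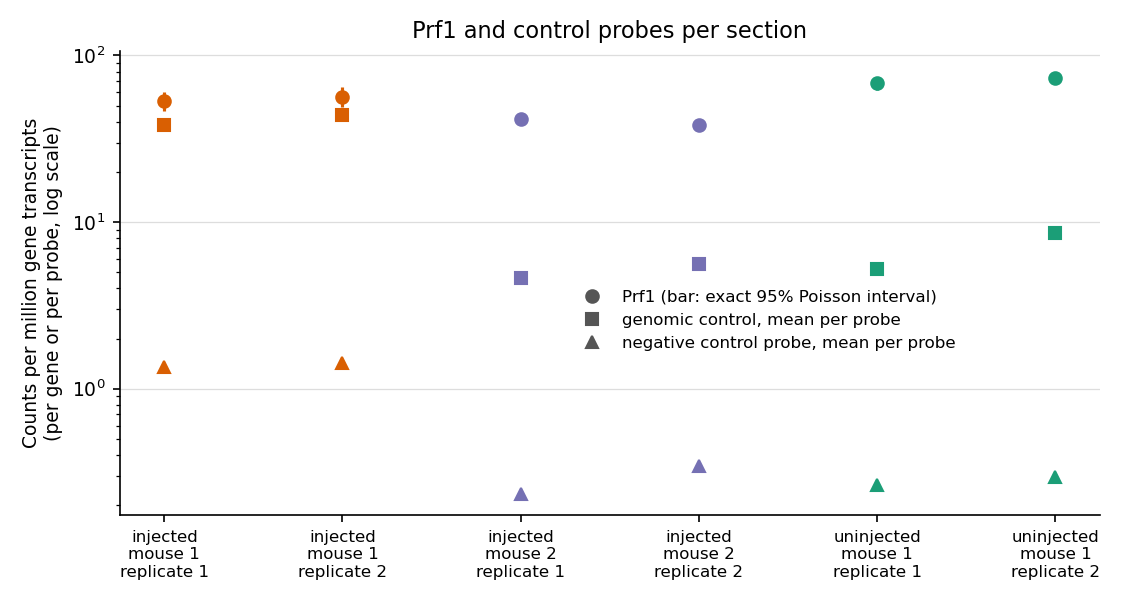
CPM (y axis, log scale) in the 6 sections for Prf1, with exact 95% Poisson intervals as bars, and the means per genomic control probe and per negative control probe. Prf1 lies between 38.3 and 73.2 in every section, while the genomic control mean lies at 38.0 and 44.0 in injected mouse 1 and at 8.60 or less in the other sections.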

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

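The tests of depth and of injection for the genes highest in injected mouse 1, the tests of misplaced melanoma cells in blood cell classes and in injected mouse 1, and every test of the erythroid-like share, were chosen only after the result was seen.

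Genomic control probes, which were in no expression test, gave 38.0 and 44.0 CPM per probe in the sections of injected mouse 1, above the uninjected sections. A search for single sections far from the others in 19 families of values found none.

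Genes with the largest ratios toward injected mouse 1 over injected mouse 2 were mostly not typical of bone. Lower depth as the only cause of the high genomic control rate in injected mouse 1 is argued against. That rate was 5.97 times that of the uninjected mouse over all cells, and 5.11 to 10.6 times in 5 ranges of 1 to 199 transcripts per cell. The uninjected mouse had a similar depth, so a part of depth in the ratios to injected mouse 2 stays open. Summed over probes, the rate was 860 CPM in injected mouse 1 and 108 in injected mouse 2 over all cells. It was 2060 and 677 in cells with 20 to 49 transcripts, and 383 and 158 in cells with 100 to 199. Injection stays open and cannot be told apart: the rate of injected mouse 2 was 0.750 times that of the uninjected mouse over all cells, but at least 2.18 times in each of these 5 ranges. Injected mouse 2 averaged 196 transcripts per cell against 42.6 in the uninjected mouse, and cells with more than 199 were in no range. A signal that tracks the genomic control probes stays open too and may account for these genes: a median of 78.0% of their mouse 1 counts lay in clusters above the genomic control limit, which held 18.9% of its gene transcripts. Those clusters alone do not account for the ratios. Without them Hamp was at -3.03, Hes5 at -3.19 and Nr1i3 at -2.68, and 1422 genes were at least doubled in mouse 1 in place of 1712. Uba1y, Onecut1 and Sox3 then had no value. Cells with fewer than 20 transcripts, which were in no cluster, stayed in these sums. Outside injected mouse 1, cells with a genomic control count carried these genes at a median log2 ratio 1.95 above that of all genes, with Slc4a1 the exception at -1.17.

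Pigment genes rose within several other cell classes of the injected mice, but only 1 of 9 in mature B-like and 2 of 8 in erythroid-like cells, and none of 10 was called by edgeR in skeletal muscle-like cells. No explanation tested was argued against, and expression by the other classes themselves was not tested. Transcripts of neighbouring melanoma cells may contribute, since the pigment genes kept their ratios to melanoma-like cells with a median absolute deviation of 0.238 on the log2 scale. Melanoma cells placed in the wrong cluster may contribute too, since 60.7% of the pigment transcripts in other classes, most of them in injected mouse 2, lay in cells with 10 or more of them, which were 4.78% of the cells. In blood cell classes (8.31%) and in injected mouse 1 (32.2%) this cannot be told apart, since melanoma-like cells with as many transcripts would give only 36.8% and 49.9%.

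The erythroid-like share was lower in both injected mice. Dilution by melanoma-like cells is argued against, since outside these clusters the injected mean was 0.0510 times the uninjected share. Less marrow in the sections cannot be told apart. Among marrow blood classes the highest injected section had 0.294 times the uninjected erythroid-like share. These classes made up 65.9% and 66.2% of kept cells in the uninjected sections and 6.33% to 18.9% in the injected ones. Whether the cells counted in them lay inside marrow was not tested, so a share among them cannot show that marrow was present. Erythroid cells hidden in other clusters are argued against, since whole sections without clustering had a median log2 ratio of erythroid genes of -4.01 in the injected mouse nearer to the uninjected one; this test replaced an earlier one that covered injected mouse 2 only. A loss of erythroid cells with injection stays open as a hypothesis, found and tested on the same data in 2 mice against 1.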

How the results depend on the processing

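Leaving out clusters above the genomic control limit, the limit of 3 times the genomic control level, the count not above melanoma-like cells and the scalings of genes were chosen after the data were seen. Named genes and lists near 0 changed sign most often, and the pigment, erythroid and B lineage lists kept their direction and their camera call with both other scalings and on leaving out any single section (leaving out an injected mouse allowed no test), but no list was called with an estimated correlation or by fry (0 higher and 0 lower in each; smallest adjusted p 0.852 and 0.748). The estimated correlation and fry rest on 1 residual degree of freedom, and the main camera test uses the same fit. Where a value below differs from the main value, the cause was not tested. In simulated data of this design, with the common dispersion for every gene, 26.2% of genes changed by a log2 of 4 were recovered. A lack of a call is therefore not read as a lack of change. The number of mice was not varied.

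Main counts were 176 higher and 226 lower genes over whole sections and 618 and 683 within classes. DESeq2 size factors gave 52 and 106, with Egfl7 at -0.12, Mcm2 -0.20, Tcf7 -0.0100 and Ttn -0.18. The DESeq2 Wald test gave 342 and 304 within classes and the same rounded values for these genes, Egfl7 -0.12, Mcm2 -0.20, Tcf7 -0.0100 and Ttn -0.18. Library totals gave 468 and 365, 57 genes higher in injected mouse 2, and Fn1 0.13, Oasl2 0.13 and Pth1r 0.21. Without the filter on low counts 1150 genes were lower within classes.

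The 6 sections as separate libraries, which treats sections of a mouse as independent, gave 762 and 755 over whole sections and 2490 and 2448 within classes. With the replicate number as a block they gave 584 and 625, and 1645 and 1760. Replicate numbers belong to different mice and do not pair sections, and deviations of the first replicates correlated at 0.366, 0.0733 and 0.183 between mice.

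Without melanoma-like cells 39 and 85 genes, 3 lower lists and 536 genes higher in mouse 2 were counted. Values then were Csf1 0.0038, Ddit3 -0.026, Entpd1 0.25, Fn1 0.32, Mcm2 -1.28, Oasl2 0.45, Pth1r 0.48 and Tcf7 -0.33, with the endothelial list at 0.24, osteoclast-regulating 0.43, skeletal muscle 0.38 and type I interferon 0.37. Without clusters above the genomic control limit 413 genes were higher, with Csf1 0.017, Cxcl12 -0.074, Fn1 0.31, Oasl2 0.28, Pth1r 0.17 and Stat2 0.16, the checkpoint list at -0.22 and cytotoxic effectors at -0.23. With kept cells only, Oasl2 was 0.0086 and Ttn -0.016. With genes at 3 or more times the genomic control level, Oasl2 was 0.0026, Pth1r 0.067 and the interferon gamma list 0.041, and 16 lists could be tested. Tested and adjusted only over genes not above melanoma-like cells, 242 genes were higher within classes. Without injected mouse 2 the matrix remodelling list was -0.32.

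Leaving out each section in turn gave 149 to 397 lower genes over whole sections, and 338 to 812 higher and 439 to 874 lower genes within classes. Ranges were -0.16 to 0.34 for Col3a1, -0.29 to 0.22 for Egfl7, -0.42 to 0.023 for Fn1, -0.30 to 0.14 for Mcm2, -0.35 to 0.17 for Oasl2, -0.49 to 0.21 for Pth1r, -0.10 to 0.46 for Tcf7, -0.35 to 0.13 for Ttn and -0.087 to 0.21 for the matrix list. The lowest whole-section count came without injected mouse 1 replicate 1 and the lowest class counts without uninjected replicate 1.

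The erythroid-like share difference, -26.5 points, was -30.1 with 50 or more transcripts per cell, -30.2 and -29.0 at resolutions 0.5 and 2, -29.8 in another subsample, -24.2 after thinning, -25.2 with z-scores and -29.4 without scaling. Melanoma-like cells differed by 12.04 points at resolution 2 in place of 24.6, and melanoma-marker cells by 7.47 after thinning in place of 32.5. Neutrophil-like cells differed by -8.61 with 10 or more transcripts and -5.09 after thinning in place of -11.6, mural-like cells by 0.273 with 50 or more and 0.372 after thinning in place of -0.837, adipocyte-like cells by 0.0153 with 10 or more in place of -0.414, and osteoblast-like cells by 0.154 with z-scores in place of -1.60. With 50 or more transcripts Tjp1 in mural-like cells was -0.45, and B precursor-like and monocyte-like cells formed no class, which left 9 classes. Prf1 was 0.84 per cell in place of -0.58.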

Other observations

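Among cells of the marrow blood classes alone, erythroid-like cells made up 11.9% and 6.87% in the injected mice and 41.8% in the uninjected mouse. The shares of the other marrow classes depend on this erythroid-like share of the denominator and are not compared here. Prf1 stood at 283, 292 and 252 CPM in monocyte-like cells of injected mouse 1, injected mouse 2 and the uninjected mouse, at 249, 273 and 265 in osteoblast-like cells, and at 6.15, 4.73 and 106 in melanoma-like cells. The 249 rests on 3 counts (exact 95% Poisson interval 51.3 to 728) and the 106 on 8 (45.6 to 208). Melanoma-like cells of the uninjected mouse carried few pigment transcripts and are not the same cells as in the injected mice.

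A set of 6 genes was followed over all tested classes, chosen after their values were seen. The circadian output gene Dbp was called lower by edgeR in 6 of 10 classes, from -5.09 to -2.02. Igfbp3 and the stress gene Ddit4 were each called higher in 8 of 11 classes, from 1.96 to 3.31 and from 1.51 to 3.05, and lay above both uninjected sections in the injected sections of all 11. Fkbp5, a glucocorticoid-induced gene, was called higher in 5 of 11 classes, from 1.39 to 2.37, while over whole sections it had a value of 0.91 ± 0.93. Cxcl10 was called higher in 5 of 11 classes and Arg1 in 4 of 8. Igfbp3 was also among the genes leading the endothelial-like cluster and Arg1 the macrophage-like one, and Cxcl10 stood at 516 and 1227 CPM in melanoma-like cells of the injected mice, above every tested class of injected mouse 2. Transcripts from such cells were not filtered here. Time of day of tissue collection was not analysed here.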
